A study of Mus musculus with 6 samples.

How the data were processed

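RNA sequencing was analysed for 6 libraries of EGFP-positive cells sorted from dorsal root ganglia of mouse embryos at 18.5 days post coitum, 3 from females and 3 from males. Per the labels' protocols, ganglia were dissociated and sorted, RNA was extracted, 10 ng of total RNA was reverse transcribed and amplified with a SMARTer ultra-low-input kit, and libraries were amplified for 12 PCR cycles and sequenced on an Illumina HiSeq instrument. The labels give each library's sex and letter and the number of embryos and ganglia pooled. Male C was deposited in a later batch of records than the other libraries, with a shortened genotype label, and was taken from 1 embryo. The libraries came from different embryos, 5 of them as pools and male C from a single embryo, so p-values measured the spread between these libraries, which in males mixes 1 animal with pools of 2 and 3.

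The authors deposited, for each library, a table of 41388 genes with coordinates, a gene length, a read count, a CPM value and an RPKM value. Per the submitters' processing notes, reads were counted per gene with featureCounts 1.4.5 of the Subread package on the mouse build GRCm38.p2. The aligner settings, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. The deposited read counts are whole numbers that sum to between 15.69 and 24.03, in units of 1e+06 reads, per library. The CPM values deposited by the authors equal the count scaled to the library's total, and the deposited RPKM values equal CPM per kilobase of the deposited gene length, which was checked for every gene. Both were therefore recomputed from the counts with normalised library sizes, and the deposited CPM and RPKM were used for that check alone. Gene symbols were taken from GENCODE release M21 by Ensembl identifier, which gave a symbol to 40254 identifiers (97.26%), and the coordinates printed are the deposited ones.

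Library sizes were scaled with edgeR 4.0.16 (TMM factors, in R 4.3.3). For levels, RPKM was averaged over the 6 libraries as 1 population, and each gene list was summarised per library by the median over its members of log2(RPKM + 0.1). Each of 28 lists was compared with the nonpeptidergic nociceptor list by an exact two-sided sign-flip permutation test over the 6 libraries (64 sign flips), with Benjamini-Hochberg adjustment over lists. This scale understates differences of low genes. For sex, genes were filtered with filterByExpr at its default settings and tested with edgeR's quasi-likelihood test, female against male, with Benjamini-Hochberg adjustment at 0.05. Lists with at least 3 tested members (26 of 29) were tested with fry and camera in limma 3.58.1 on log2 CPM with a prior count of 2. Fry's p tests whether the members of a list move, on balance, one way; camera compares a list with the other genes and was run with a preset correlation of 0.01 and with an estimated correlation. All tests were two-sided. The biological coefficient of variation came from the same edgeR fit. Counting intervals and the limit allowed by a count of 0 (3 counts of the library total) are at the 95% level and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

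The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names all genes called between sexes if 30 or fewer (otherwise the 15 of smallest p in each direction), the members of the sort, Y chromosome and X inactivation escape lists, the 8 highest members of both nociceptor lists, the 3 highest members, the lowest member and the member of smallest p for sex of each other list, the 10 genes of highest count share, and the 10 tested genes of highest biological coefficient of variation with a mean of 10 CPM or more. A selection of the genes this rule gives is printed, and other genes named were chosen after their values were seen. The alternatives chosen then were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersions, the letter as a block, the number of pooled embryos as a covariate, each library left out in turn and a threshold of 0.10. For list levels they were CPM in place of RPKM, a pseudocount of 1, the mean over members, RLE factors, members passing the filter alone and each library left out. A principal component as a covariate, offsets for GC content and the escape list without Xist were added after the data were examined. GC content was that of annotated transcripts, available for 99.4% of tested genes, and its trend in each library was removed by a lowess curve with a span of 0.3. The edgeR and fry steps were tested on simulated data with 200 changed genes drawn from the libraries' means and sizes. In these, 1 shifted list of simulated genes gave an unadjusted fry p of 0.000878. After Benjamini-Hochberg adjustment over the simulated lists, 0 of 20 unshifted lists had a fry p below 0.05.

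The 6 libraries were the only samples analysed. No EGFP transcript was quantified, since the gene tables used hold mouse genes, and isoforms could not be read from gene counts.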

Results

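RNA was sequenced from neurons sorted out of embryonic mouse dorsal root ganglia, the clusters of sensory neurons beside the spinal cord. The mice were C57BL/6 embryos at 18.5 days post coitum, and the ganglia came from lower thoracic to the first sacral levels. The sorted cells carried EGFP, a green fluorescent protein switched on in cells of the Ret population that expressed Cre recombinase from the Nav1.8 locus. Ret is the signalling receptor for glial cell line-derived neurotrophic factors, and Nav1.8, encoded by Scn10a, is a sodium channel of pain-sensing neurons. The 6 libraries comprised 3 from female and 3 from male embryos, each named by its sex and the letter A, B or C. Female A, B and C and male A each pooled 40 ganglia from 2 embryos, male B pooled 60 ganglia from 3 embryos, and male C held 20 ganglia from 1 embryo. Total counts, in units of 1e+06 reads, were 15.81, 24.03 and 23.00 in female A, B and C, and 22.38, 23.56 and 15.69 in male A, B and C. Between 19526 genes (male C) and 21755 genes (female C) had at least 1 read, out of 41388 genes listed in each library. Coordinates are those deposited with the counts, on the mouse build GRCm38.p2.

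The genes that define the sort, Scn10a and Ret, and the most abundant genes of both nonpeptidergic and peptidergic nociceptors were expressed in every library. Scn10a (ENSMUSG00000034533, chromosome 9, 119608456 to 119719032) averaged 119 ± 16.8 RPKM, and Ret (ENSMUSG00000030110, chromosome 6, 118151748 to 118197744) averaged 27.8 ± 3.83 RPKM (SD, n = 6). The labels do not state whether these embryos carried 1 or 2 copies of the altered Ret allele, so the Ret level cannot be read as that of the unaltered gene. Among nonpeptidergic nociceptor genes the itch receptor gene Mrgprx1 averaged 217 ± 24.02 RPKM, the artemin co-receptor gene Gfra3 203 ± 47.1 RPKM and the ATP-gated channel gene P2rx3 125 ± 23.7 RPKM (SD, n = 6). Among peptidergic nociceptor genes Calca, which encodes calcitonin gene-related peptide, averaged 974.7 ± 164 RPKM and the galanin gene Gal 321 ± 43.5 RPKM (SD, n = 6). These values describe which sensory neuron classes and which other cells were represented in the sorted population. No other population was analysed here, so gene lists were compared with each other within libraries.

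**Figure D1:**
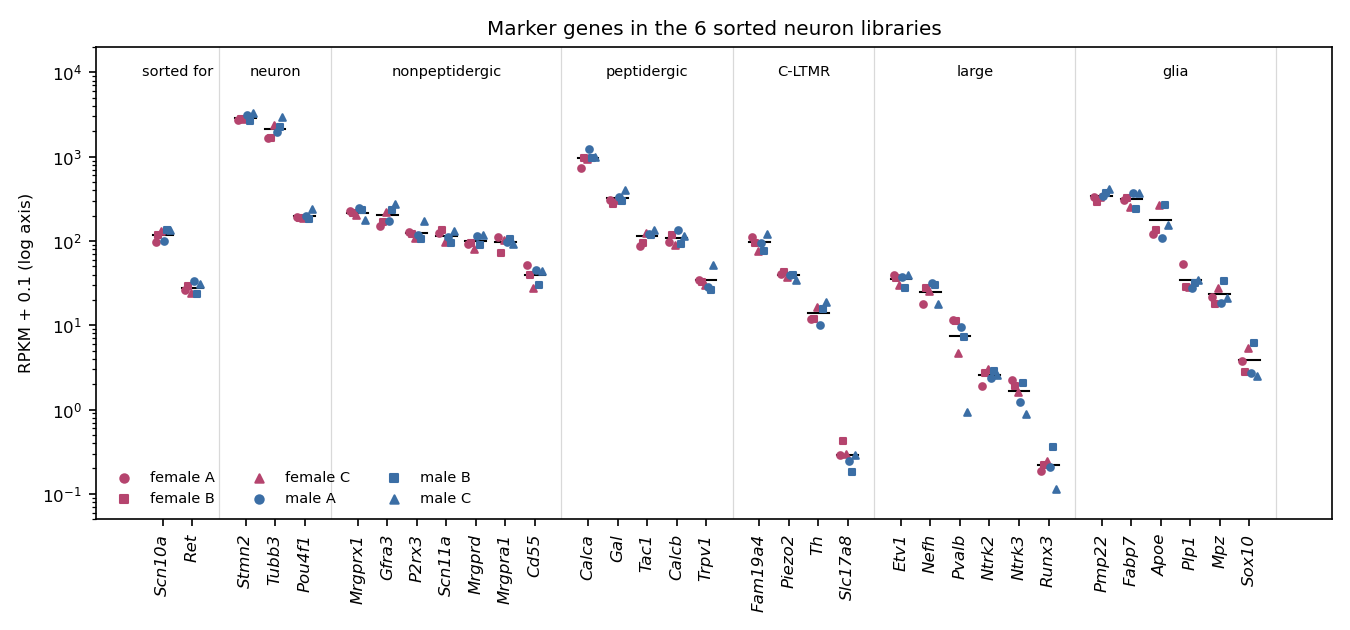
RPKM plus 0.1 (log axis) of marker genes in the 6 libraries, 1 point per library and a bar at the mean; C-LTMR stands for C-low-threshold mechanoreceptor, large for large-diameter mechanoreceptor and proprioceptor, and sorted for marks the 2 genes that define the sort. Nociceptor genes such as Mrgprx1 (217 RPKM) and Calca (974.7 RPKM) lay far above Runx3 (0.123 RPKM), and Pvalb was lowest in male C.

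The nonpeptidergic list held 22 genes and had a median log2(RPKM + 0.1) of 3.02 ± 0.13 (SD, n = 6 libraries). After Gfra3 and P2rx3 its members of highest level were the sodium channel gene Scn11a at 115 ± 16.9 RPKM, the receptor genes Mrgprd at 98.5 ± 15.1 and Mrgpra1 at 97.0 ± 13.7 RPKM, Cd55 at 39.7 ± 9.36 RPKM and Ret. The lowest member of the list was Mrgprb4 at 0.0493 ± 0.0599 RPKM. Reads of the closely related Mrgpr genes may be split between copies, because the treatment of reads that match several places is not given in the sources used here. The peptidergic list of 15 genes lay higher than the nonpeptidergic list by 1.73 ± 0.24 log2 units in 6 of 6 libraries (exact sign-flip permutation test, two-sided p = 0.03125, adjusted p = 0.035). Its members included the substance P gene Tac1 at 113 ± 19.1 RPKM, Calcb at 107 ± 18.3 RPKM, the p75 receptor gene Ngfr at 45.8 ± 25.6 RPKM, the capsaicin receptor gene Trpv1 at 33.9 ± 9.45 RPKM and Adcyap1 at 33.4 ± 2.01 RPKM, while Sstr2 lay at 0.161 ± 0.0805 RPKM. The sort genes Scn10a and Ret lay higher by 2.82 ± 0.13 log2 units. Pan-neuronal genes, led by Stmn2 at 2897 ± 248 RPKM and Tubb3 at 2153 ± 504 RPKM, lay higher than the nonpeptidergic list by 4.56 ± 0.23 log2 units, and the receptors for glial cell line-derived factors and neurotrophins by 0.48 ± 0.12 log2 units. Over the 28 lists compared in this way, 25 passed an adjusted p of 0.05, 19 of them lower and 6 higher than the nonpeptidergic list. The test asks only whether sets of different genes keep their order of level across libraries. Unrelated gene sets can pass it for that reason alone, and lists of random genes were not tried. Ret also belongs to the sort, receptor and nonpeptidergic lists, so these lists are not separate. The smallest p that 6 libraries allow is 0.03125, and lists differ in their genes, so a difference between lists describes levels and not numbers of cells. With the mean over members in place of the median, the receptor list for glial cell line-derived factors and neurotrophins changed direction, to -0.22 log2 units.

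Transcripts of other sensory neuron classes were lower as groups, although single members were abundant. The C-low-threshold mechanoreceptor list lay below the nonpeptidergic list, at -0.79 ± 0.35 log2 units in 6 of 6 libraries, with Fam19a4 at 95.8 ± 18.7 RPKM, the touch channel gene Piezo2 at 39.2 ± 2.90 RPKM and the tyrosine hydroxylase gene Th at 14.04 ± 3.42 RPKM, but the vesicular glutamate transporter gene Slc17a8 at 0.186 ± 0.0791 RPKM. The large-diameter mechanoreceptor and proprioceptor list lay at -2.24 ± 0.39 log2 units. In this list Etv1 averaged 34.9 ± 4.97 RPKM, the neurofilament gene Nefh 25.01 ± 6.08 RPKM and the parvalbumin gene Pvalb 7.45 ± 4.14 RPKM, while the TrkB and TrkC receptor genes Ntrk2 and Ntrk3 averaged 2.49 ± 0.413 and 1.56 ± 0.520 RPKM and Runx3 0.123 ± 0.0802 RPKM. The list of thermal and cold receptors lay at -2.89 ± 0.44 log2 units, with Trpv1 and Trpv2 (20.2 ± 4.68 RPKM) high and the cold receptor gene Trpm8 at 0.894 ± 0.402 RPKM and Trpa1 at 0.447 ± 0.107 RPKM (SD, n = 6 throughout; each exact permutation p = 0.03125, adjusted p = 0.035).

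Channel and receptor lists were led by a few genes each. Among voltage-gated sodium channels Scn10a, Scn11a and the beta subunit gene Scn2b (91.4 ± 38.3 RPKM) were highest; the list did not pass the test against the nonpeptidergic list (-0.63 ± 0.42 log2 units, lower in 5 of 6 libraries, exact permutation p = 0.0625, adjusted p = 0.0673). It was lower in the exact permutation test with the mean over members (-0.62 log2 units, p = 0.03125) and with members passing the expression filter (-0.86 log2 units, p = 0.03125). Potassium channel genes, at -1.53 ± 0.52 log2 units, were led by Kcnk18 (29.9 ± 5.60 RPKM), Kcnd1 (25.4 ± 2.58 RPKM) and Kcnip4 (19.04 ± 2.98 RPKM). In the opioid, cannabinoid, serotonin and purinergic receptor list, at -1.93 ± 0.22 log2 units, P2rx3 was followed by the serotonin receptor gene Htr3b at 30.0 ± 3.26 RPKM and the cannabinoid receptor gene Cnr1 at 15.3 ± 2.45 RPKM. Neuropeptide genes beyond Calca, Gal and Tac1 were lower, and the list lay at -1.27 ± 0.41 log2 units. Sex steroid receptor and synthesis genes lay at -4.20 ± 0.29 log2 units, with the membrane estrogen receptor gene Gper1 at 15.2 ± 5.30 RPKM, Srd5a1 at 9.03 ± 0.771 RPKM and Hsd3b1 at 0.0339 ± 0.0530 RPKM (SD, n = 6).

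Glial transcripts were abundant in the sorted cells, and the lists of other cell types lay far below the nociceptor lists. Satellite glia and Schwann cell genes lay 0.29 ± 0.40 log2 units from the nonpeptidergic list, above it in 4 of 6 libraries (exact permutation p = 0.1875, adjusted p = 0.194). The myelin gene Pmp22 averaged 346 ± 43.8 RPKM, the radial glia gene Fabp7 311 ± 56.1 RPKM and the lipoprotein gene Apoe 175 ± 72.2 RPKM, while Gfap averaged 0.0646 ± 0.0901 RPKM (SD, n = 6). With only members that passed the expression filter the glial list lay above the nonpeptidergic list in the test, by 0.63 log2 units (exact permutation p = 0.03125). Fibroblast and meningeal genes lay at -2.71 ± 0.30 log2 units, with the proteoglycan gene Dcn high at 133 ± 13.8 RPKM and Twist1 at 0.0578 ± 0.0639 RPKM. Endothelial and pericyte genes lay at -4.54 ± 0.37, blood cell genes at -4.96 ± 1.22, skeletal muscle genes at -5.46 ± 0.34, immune cell genes at -5.44 ± 0.15, sympathetic neuron genes at -6.07 ± 0.38 and cartilage and bone genes at -6.07 ± 0.24 log2 units (SD, n = 6; each exact permutation p = 0.03125). Blood cell genes held the exception under another choice: with only members that passed the expression filter the difference was 1.04 log2 units (exact permutation p = 0.1875). The sympathetic list nevertheless held Chga at 68.2 ± 28.4 RPKM, and its noradrenergic member Dbh lay at 0.0101 ± 0.0248 RPKM. Spinal cord genes lay at -6.34 ± 0.13 log2 units with a list median at the pseudocount, so the size of this difference depended on it. In some libraries the medians of the blood cell, sympathetic neuron, cartilage and bone and Y chromosome lists also lay at the pseudocount. The size of their differences depended on it too. A count of 0, as for Olig2 in each library, allows a level of up to 0.125 CPM in female B and 0.191 CPM in male C, for counting error only.

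**Figure D2:**
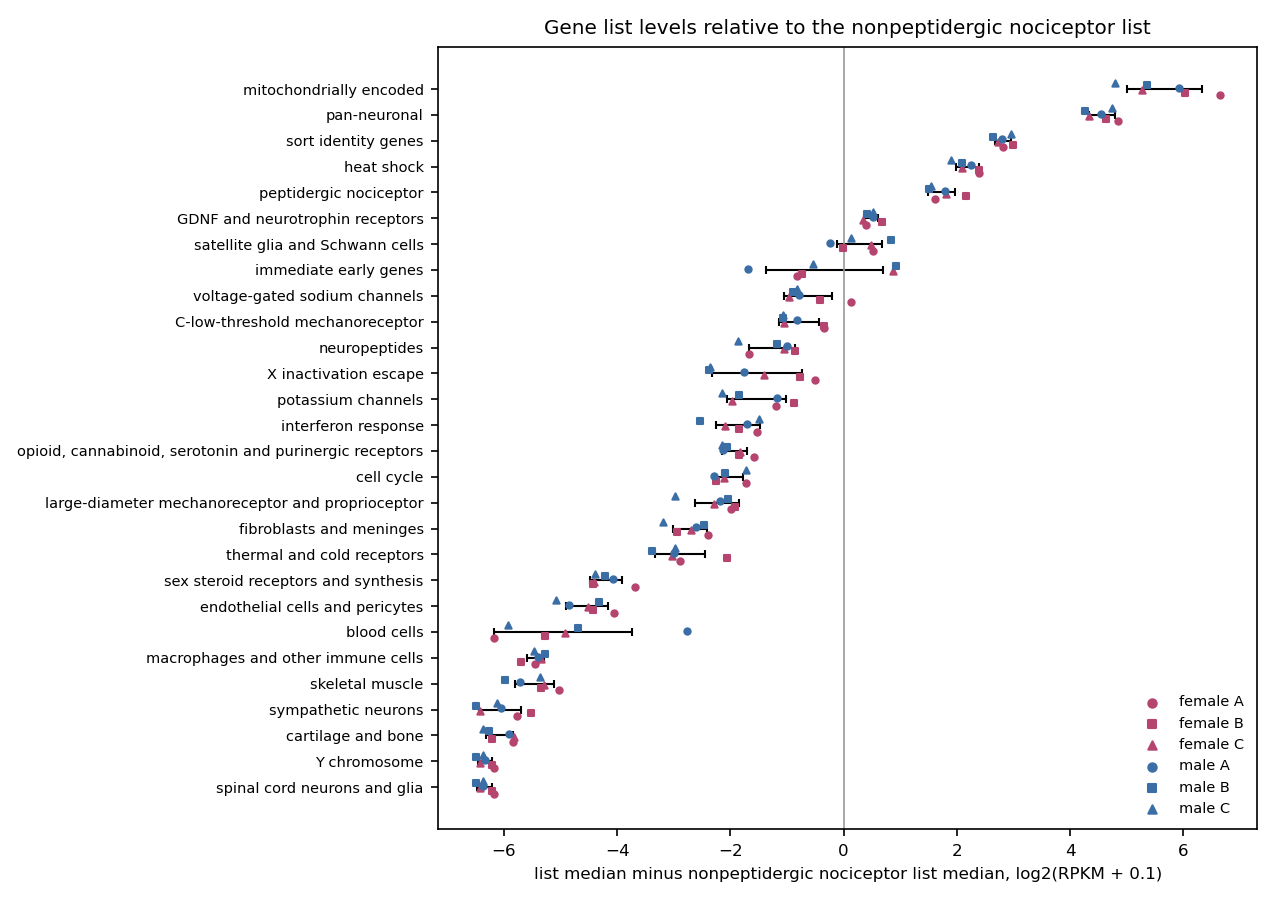
Median log2(RPKM + 0.1) of each gene list minus that of the nonpeptidergic nociceptor list (horizontal axis, log2 units), 1 point per library with mean and SD of the 6 libraries in black. The pan-neuronal list lay at 4.56 and the spinal cord list at -6.34, and the immediate early and blood cell lists were spread widest.

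Cell state lists were also read. Cell cycle genes lay at -2.04 ± 0.25 log2 units from the nonpeptidergic list, with the proliferation marker gene Mki67 at 0.341 ± 0.264 RPKM and Pcna at 11.2 ± 1.86 RPKM. Interferon response genes lay at -1.87 ± 0.40 log2 units and heat shock genes at 2.19 ± 0.20 log2 units, led by Hspa8 at 235 ± 42.2 RPKM. Immediate early genes, which are switched on within minutes of stimulation, varied most between libraries apart from blood cell genes. Fos averaged 145 ± 91.5 RPKM, and the list's difference from the nonpeptidergic list was -0.33 ± 1.04 log2 units (exact permutation p = 0.53125). Mitochondrially encoded genes lay at 5.67 ± 0.66 log2 units, with mt-Cytb at 5027 ± 1217 RPKM and mt-Nd1 at 4176 ± 1161 RPKM; mt-Co2, mt-Co3 and mt-Atp6 averaged 0.0674 ± 0.107, 0.0934 ± 0.0964 and 0.0103 ± 0.0252 RPKM (SD, n = 6). These 3 genes had 0 to 4 reads per library, and since the strand setting and the treatment of reads that match several places are not given in the sources used here, their values cannot be read as expression levels. The X inactivation escape list lay at -1.53 ± 0.79 and the Y chromosome list at -6.34 ± 0.13 log2 units over libraries of both sexes. By share of counts the leading genes were Dpysl2, a cytoskeletal regulator of growing axons, at 1.29 ± 0.193% of counts, Gm42418 at 0.965 ± 0.699%, Actb at 0.870 ± 0.111%, Tuba1a at 0.781 ± 0.0724% and Map1b at 0.779 ± 0.112% (SD, n = 6). Gnb1, mt-Rnr2, mt-Cytb and Stmn2 were also among the 10 genes of highest share.

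Female and male nociceptors differed in the sex-linked genes, and no autosomal gene passed the test between them. The question was which transcripts differ by sex in these neurons before birth. Called by edgeR and expressed in the male libraries were 4 genes of the Y chromosome. Ddx3y, an RNA helicase gene, stood at 136 ± 16.2 CPM and the translation factor gene Eif2s3y at 49.6 ± 2.51 CPM (SD, n = 3). The histone demethylase genes Uty and Kdm5d stood at 36.5 ± 5.13 and 15.8 ± 2.93 CPM (SD, n = 3). In the female libraries Xist, the noncoding RNA that silences an X chromosome, stood at 157 ± 52.3 CPM, against 0.654 ± 0.293 CPM in the male libraries (SD, n = 3). These 5 genes were called among 15026 tested, 1 higher in female and 4 higher in male libraries, by edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

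Xist (ENSMUSG00000086503, chromosome X, 103460375 to 103483217) had a log2 fold change, female over male, of 7.83 with a standard error of 0.38 (edgeR adjusted p = 6.85e-06). Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629) had a log2 fold change of -9.60 with a standard error of 0.40 (edgeR adjusted p = 3.43e-06). Eif2s3y (chromosome Y, 1010543 to 1028847) was at -8.55 (standard error 0.37), Uty (chromosome Y, 1096861 to 1245759) at -8.77 (standard error 0.48) and Kdm5d (chromosome Y, 897788 to 956786) at -7.82 (standard error 0.56). Raw reads of Ddx3y were 0, 5 and 6 in female A, B and C and 3378, 2952 and 1944 in male A, B and C, so these folds rest on few reads in one sex and depend on the prior count of the fit. Xist had 3441, 3164 and 2937 reads in the female and 20, 17 and 5 in the male libraries. Xist overlaps its antisense partner Tsix, and the strand setting of the counting is not given in the sources used here. Every one of the 6 libraries carried the sex-linked transcripts of the sex in its label.

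**Figure D3:**
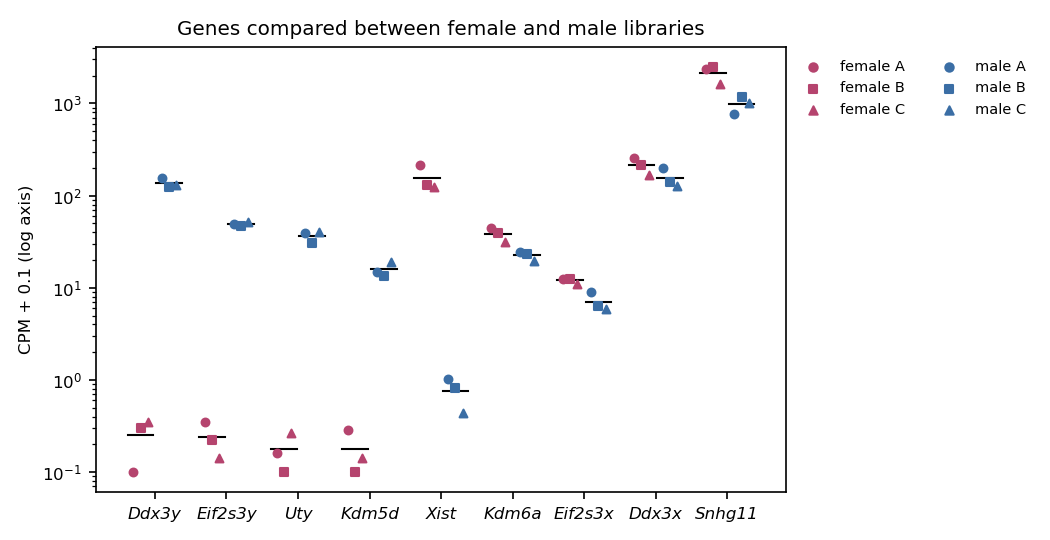
CPM plus 0.1 (log axis) of 9 genes in the female (left of each gene) and male (right) libraries, 1 point per library and a bar at the mean of each sex. Ddx3y, Eif2s3y, Uty and Kdm5d were near 0 in female libraries and Xist was near 0 in male libraries, while Kdm6a, Eif2s3x, Ddx3x and Snhg11 differed by less.

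No autosomal gene was called by edgeR quasi-likelihood test, with 149 autosomal genes at an unadjusted p below 0.05, 1 autosomal gene called by DESeq2 and 0 by limma-voom. Over all chromosomes 166 genes had an unadjusted p below 0.05, 118 of them higher in female libraries, where 751 would be counted among 15026 tests with no difference. The DESeq2 gene was Snhg11, the host gene of small nucleolar RNAs, named here after its values were seen (chromosome 2, 158375638 to 158386145). Snhg11 averaged 2148 ± 446 CPM in female and 975.1 ± 205 CPM in male libraries, a log2 fold change of 1.14 with a standard error of 0.21 (edgeR adjusted p = 0.681, DESeq2 adjusted p = 0.00526), and over the alternatives run its adjusted p lay between 0.000108 with no filter and 0.99998 without male C. Without the filter on low counts edgeR called 12 genes, 3 higher in female and 9 in male libraries, of which 6 were autosomal: Snhg11, Psca and the haemoglobin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2. The haemoglobin genes have near-identical copies and were highest in male A, and Psca had 48 reads in female C and 0 in the other libraries. In simulated data with this design 33 of 100 genes changed by 2-fold and 94 of 100 changed by 4-fold were recovered, with 9 false calls among 14761 genes tested, so most changes of 2-fold or less would have been missed. The simulated genes varied independently, without the differences that the real libraries share across genes, and changed genes had a mean of at least 1 CPM. Recovery in the real data may therefore be lower.

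X-linked genes that are known to escape X inactivation were each higher in female libraries, although the list missed the threshold of the directional fry test. All 12 tested members of the list had a positive log2 fold change, with a median of 0.27. Besides Xist they included the histone demethylase gene Kdm6a at 38.1 ± 6.61 CPM in female and 22.3 ± 2.39 CPM in male libraries, a log2 fold change of 0.77 with a standard error of 0.20, Eif2s3x at 0.77 with a standard error of 0.24 and Ddx3x at 0.46 with a standard error of 0.22 (n = 3 per sex). Of the 12 members 1 was called over all genes and 3 when adjusted over the list alone. The directional fry test gave an adjusted p of 0.0550, and camera gave an adjusted p of 2.37e-08 with a preset correlation and an adjusted p of 0.279 with an estimated correlation. Under 3 other scalings or filters the fry test passed the threshold, at an adjusted p of 0.0497 with upper-quartile factors, 0.0383 with no filter and 0.0492 with a CPM filter, within a range over the alternatives of 0.0125 to 0.324. Without Xist, an alternative chosen after the data were examined, 11 of 11 members were higher in female libraries with a median log2 fold change of 0.27, and 1 member was called when adjusted over the list alone. That list gave a fry p of 0.0323, not adjusted over lists, and a camera p of 6.26e-06 with a preset correlation and 0.0389 with an estimated correlation.

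The X chromosome as a whole did not stand apart. The 551 tested X-linked genes other than Xist and Tsix had a median log2 fold change of 0.05, against -0.01 for 14467 other genes, and 56.8% of X-linked genes were higher in female libraries against 48.9% of the others (camera p = 0.192 with a preset correlation and p = 0.6247 with an estimated correlation). This difference of medians rested on single libraries. It was 0.11 without female C (camera p = 0.00582) and 0.10 without male A (camera p = 0.0171), with p = 0.274 and p = 0.384 with an estimated correlation, and -0.01 without female A and -0.00 without male B.

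Among the other 24 lists tested for sex none passed, the adjusted p of the fry test lying between 0.429 and 0.976. The Y chromosome list was called (4 of 4 tested members higher in male libraries, median log2 fold change -8.66, fry adjusted p = 2.63e-05, camera adjusted p = 0.00586 with an estimated correlation). In the 24 lists 0 members were called over all genes by edgeR and 0 by DESeq2 or limma-voom, with 5 members at an unadjusted p below 0.05, and 1 member, the endothelial receptor gene Tek, was called when adjusted over the list alone. Tek stood at 1.51 ± 0.996 CPM in female and 0.230 ± 0.0802 CPM in male libraries (SD, n = 3), with female A highest at 2.65 CPM, and its log2 fold change was 2.65 with all libraries and 1.99 without female A. Nociceptor lists gave small values, with a median log2 fold change of -0.11 over 20 nonpeptidergic and -0.07 over 14 peptidergic genes, and sex steroid receptor and synthesis genes of -0.02 over 7 genes. Blood cell genes had a median log2 fold change of -1.88 (fry adjusted p = 0.976), a value that rested on male A. Summed haemoglobin genes stood at 994 CPM in male A and 129 and 32.3 CPM in male B and C. In female A, B and C they stood at 38.1, 98.1 and 176 CPM. The median and mean log2 fold change differed in sign for 3 lists, those of large-diameter neurons, of receptors for glial cell line-derived factors and neurotrophins, and of sex steroid genes, all near 0.

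The main axes of variation between libraries did not follow sex. The pair of libraries with the highest correlation of log2 CPM across genes was female C and male B (0.990), and the lowest was female A and male B (0.965). The first principal component held 37.3% of the variance and set female C and male B (36.8 and 42.6) apart from female A, female B and male A (-34.8, -18.1 and -25.6). The second held 30.0% and set male C (59.8) apart from the other 5 libraries. Among tested genes with a mean of 10 CPM or more, the largest biological coefficients of variation within sex belonged to Chodl (0.907), Pgls (0.830), Rbfa (0.798), the haemoglobin genes Hbb-bs (0.762), Hbb-bt (0.761), Hba-a1 (0.760) and Hba-a2 (0.730), Fosb (0.741), Gm10800 (0.736) and Car3 (0.732), against a common value of 0.253. Chodl stood at 0.0673 CPM in male C and between 11.9 and 41.8 CPM in the other libraries, and Hbb-bs at 568 CPM in male A and between 19.05 and 104 CPM in the others. Pgls stood at 72.3 CPM in female C and 68.8 CPM in male B and between 6.08 and 6.93 CPM in the others.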

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

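The tests of chance, of depth for Chodl, of glia and of the size of difference left after removing GC or length trends in the genes called for a split were chosen after the results were seen, as was each pattern weighed; the other tests were set before their own values were computed. Among 132 levels and library measures of the 6 libraries, 10 had 1 library far from the other 5, and 8 of the 10 were in male C. A rate of 1 in 20 would give about 6.6, but that rate cannot be taken to hold here. The measures included the 10 genes of highest biological coefficient of variation, picked from these same data, and Chodl and Car3 among them were flagged. Measures also overlapped, as with the large-diameter list and its member Pvalb.

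Chodl, a membrane protein gene, was nearly absent from male C, at a log2(CPM + 0.1) of -2.58, against 3.58 to 5.39 in the other libraries. Male C had 1 read, with a Poisson interval of 0.0253 to 5.57. Lower depth is argued against, since 190 reads would be expected from the lowest share in the other libraries, and so is GC content, since the lowest other library stayed 181-fold higher after that trend was removed (177-fold before, with a counting interval that allows 34.1-fold). For a smaller share of large-diameter neurons, 9 of 14 tested members of that list were lowest in male C, between the limits set beforehand for and against. These members fell far less than Chodl. Pvalb stood at 0.875 CPM in male C against 4.74 to 11.8 CPM elsewhere, and Nefh at 70.1 against 71.0 to 126 CPM, while Whrn was highest in male C. Calb1 was also low, at 4.71 CPM in male C against 18.5 to 27.7 CPM elsewhere. How much of each member came from the cells that carry Chodl is not known. The size of the list's fall therefore cannot decide whether fewer such cells account for the drop. For the whole drop or a part of it, a smaller share cannot be told apart from a change in the gene itself. Male C is also the 1 library from a single embryo and of later deposit, and neither of these was testable.

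In the same library the large-diameter mechanoreceptor and proprioceptor list was low, at a median log2(RPKM + 0.1) of 0.0783 against 0.81 to 1.14 elsewhere, as were Car3 (log2(CPM + 0.1) of -0.65 against 2.89 to 4.82) and Pvalb (log2(RPKM + 0.1) of -0.0883 against 2.22 to 3.51). The heat shock list was lowest in male C, at 4.95 against 5.19 to 5.30. Male C was highest for Trpv2, at 4.89 against 4.11 to 4.28, for Scn2b, at 7.39 against 6.11 to 6.47, and for Gper1, at 4.69 against 3.49 to 3.84. The list of thermal and cold receptors was highest in female B, at 0.82 against -0.20 to 0.08, and Top2a was highest in female A, at 2.43 against 1.53 to 1.84. In female B the median of the thermal list was the value of Trpm8, at 1.67 RPKM against 0.512 to 0.908 RPKM elsewhere. Trpm2 and Trpa1 were also highest in female B, but Trpv2 was lowest there.

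Splitting the 6 libraries in the 10 possible ways into 3 and 3, the split by sex called 5 genes and 1 other split called 639, so 2 of the 10 splits gave as many genes; the highest other count was 639, and 10 splits are too few for a share under 0.05. The other 8 splits called 0 genes by edgeR, with 144 to 1808 genes at an unadjusted p below 0.05. The split with 639 calls set female C, male B and male C against female A, female B and male A, and points to a structure of the samples other than sex.

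Of those 639 genes, 404 were higher with female C, male B and male C and had a median transcript GC content of 56.7%, and 235 were lower with a median of 42.5%, against 49.2% of genes not called. After the trend of each library on GC content was removed, 0.469% of the calls remained, which suggests GC content bias as a candidate explanation for part of the pattern. The calls ended because the median log2 difference of the 639 genes fell from 0.73 to 0.42 while its standard error was 0.15 before and 0.14 after. Of that median 57.1% was left (bootstrap interval over genes 55.3 to 60.6%, which treats genes as independent). Genes at an unadjusted edgeR p below 0.05 fell from 4187 to 2194. The trend removed thus covered part of the difference and not the whole. Whether GC content acted beyond that trend stays open. Gene length as the whole cause is argued against, since removing its trend left 93.4% of the median (91.9 to 96.1%), at 0.68, with a standard error of 0.14 and 404 genes called, 55.6% of the 639 among them, and a part played by length stays open. The glial list differed by 0.119 of the difference of the immediate early genes (bootstrap interval -0.02 to 0.50), a ratio that does not measure the share of neurons. A lower share of neurons with female C, male B and male C would lower the 14 pan-neuronal genes. Instead 9 of 14 were higher, with a median log2 difference of 0.12 and 0 called, so that prediction was not met for these libraries together. Among glial genes 12 of 17 were higher, so more glia stays open. The pan-neuronal list median, as log2(RPKM + 0.1), was 7.44 in female C and 7.435 in male B. It was 7.80 in male C and 7.52 to 7.70 in the others. The glial list median was highest in female C and male B, at 3.58 and 4.02, against 2.81 to 3.37 elsewhere. A lower share of neurons in female C and male B alone thus stays open. GC trends were not removed from these values.

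Immediate early genes stood out in that split, with 19 of 19 tested members higher with female C, male B and male C, a median log2 difference of 1.82, and 12 called. GC content was unlikely to be their whole cause, since 76.7% of that median was left after its removal, at 1.39, with 18 of 19 members higher. However, 0 members were then called by edgeR. The bootstrap interval over genes, 70.1 to 93.1%, treats genes as independent. These members moved together, at a correlation of 0.852 estimated by camera in the fit for sex. The interval is therefore too narrow, and it leaves out the spread between libraries. The lowest unadjusted edgeR p among them was 0.000104 before and 9.41e-05 after. Calls over all genes fell from 639 to 3, so the adjustment over all genes also bears on these lost calls. Male C shared little of this over the list, whose median log2(RPKM + 0.1) was 3.98 in female C and 4.10 in male B, but 2.51 in male C, against 2.03, 2.14 and 1.36 in female A, female B and male A; Fos was an exception, at 482 CPM in male C beside 587 and 527 CPM in female C and male B, and 76.8 to 189 CPM in the others. In the same split the glial genes Apoe, Mbp and Egr2, the last also on the immediate early list, were called higher, and the mitochondrially encoded genes mt-Nd5 and mt-Nd6 (list median log2 difference -0.53) and the heat shock genes Dnaja1 and Hsph1 (list median -0.32) were called lower. From the other lists with at least 3 tested members, Gfra3, Th and Kcnk10 were called higher and Kcnd3, Kcnc2 and Ddx3x lower. Differences in cell make-up or RNA quality stay open. Ribosomal RNA genes, mitochondrial ones and Gm26917 included, held 0.951% and 1.08% of counts in female C and male B. They held 0.4725% in male C and up to 0.807% in the others. Long noncoding RNA genes held 2.71% and 2.95% in female C and male B, against 1.39 to 1.79% elsewhere. The cause of these shares was not tested. Apart from the share of neurons, no biological explanation was tested.

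Haemoglobin transcripts were highest in male A, at 994 CPM summed over genes against 32.3 to 176 CPM in the other libraries. Red blood cells in male A are a candidate source, since the summed CPM of the erythroid genes of the list fixed beforehand that are not haemoglobins was 3.20-fold higher there than in the next library, at 29.3 CPM from 640 reads against 9.15 CPM. A single member can carry such a sum, so it does not show that each of these genes was higher. The sort on EGFP was aimed at other cells, but Pmp22 of the glial list and Dcn of the fibroblast list were abundant after it. It thus cannot be taken to have removed red blood cells, and RNA carried over from them was not tested.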

How the results depend on the processing

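Of these alternatives, the principal component, the GC offsets and the list without Xist were chosen after the data were examined. The 5 genes called between sexes were kept under each alternative, whose counts were 5 to 7 genes except for 12 with no filter, where more genes were tested, and 6 of those 12 were autosomal. The autosomal count was 0 except for that 6 and for 1 with DESeq2. Gm29650, which is not autosomal, was also called higher in male libraries with DESeq2, with limma-voom and with no filter. The letters A, B and C did not pair the libraries, since the deviations from the sex means of the libraries sharing a letter correlated at 0.28, -0.29 and -0.08; with the letter as a replicate block 5 genes and 2 lists were called. Lists called numbered 2, the Y chromosome and X inactivation escape lists, with upper-quartile factors, no filter, the CPM filter, the replicate block and a threshold of 0.10, and 1 with each library left out. The escape list's adjusted p ranged from 0.0125 with the replicate block to 0.324 without male B. The X chromosome difference ranged from -0.0107 to 0.107 over the libraries left out and passed the preset test without female C and without male A. List levels passed for 25 lists with CPM, a pseudocount of 1, the mean over members or RLE factors and for 26 with members passing the filter alone. Of the lists past the threshold 2 changed direction, the receptors for glial cell line-derived factors and neurotrophins at -0.22 with the mean over members and blood cells at 1.04 with members passing the filter alone. The causes were not tested. Among log2 fold changes of named genes recomputed, 1907 kept their side of the threshold, and 4, those of haemoglobin genes with no filter, passed it. Genes past the threshold kept their direction, while a change of direction among genes not past it was not counted. Lists and the X chromosome were not recomputed with DESeq2 or robust dispersions. Leaving out a library leaves 5, for which the smallest exact permutation p is 0.0625, so list levels were compared there by size alone.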

Other observations

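The genes in this part were chosen after the data were seen, and no hypothesis is drawn from them. Hox genes, which record position along the body axis, were expressed mainly from the middle of the clusters to paralogue group 10. Of 39 Hox genes, 15 had a mean above 1 RPKM, 14 of the 30 in groups 1 to 10 and 1 of the 9 in groups 11 to 13. Hoxd10 was highest at 21.5 ± 4.19 RPKM, followed by Hoxb7 at 10.6 ± 1.47, Hoxd8 at 9.79 ± 1.61, Hoxa10 at 9.36 ± 1.84, Hoxa7 at 8.92 ± 1.34 and Hoxc10 at 8.53 ± 0.649 RPKM (SD, n = 6). In the posterior groups Hoxd11 stood at 3.17 ± 0.568 RPKM and Hoxc11 at 0.410 ± 0.250 RPKM, and Hoxa11, Hoxa13 and Hoxd13 had no reads in the 6 libraries. Hoxd1 was the one gene of groups 1 to 3 above 1 RPKM, at 3.57 ± 0.569 RPKM.

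Sensory neuron transcription factors were expressed at uneven levels. Pou4f1 averaged 197 ± 21.6 RPKM and Isl1 173 ± 15.5 RPKM, ahead of Klf7 at 74.7 ± 3.64, Isl2 at 47.4 ± 7.26, Prrxl1 at 44.9 ± 9.05, Prdm12 at 19.8 ± 4.26, Pou4f3 at 17.2 ± 1.5001, Pou4f2 at 8.51 ± 1.32 and Runx1 at 7.71 ± 1.22 RPKM (SD, n = 6). Cux2 averaged 3.78 ± 0.828 RPKM, Tlx3 0.819 ± 0.267 RPKM and Neurog1, a factor of neuron birth, 0.00422 ± 0.0103 RPKM.

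Cox5a had 272 reads in male C and 1388 to 3163 in the other libraries, and mt-Rnr1 had 2801 reads in male C and 14669 to 25117 in the others. Gm42418 had 478403 reads in male B and 381338 in female C, and 65771 to 170928 in the other libraries.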
